A study of Homo sapiens with 10 samples.

How the data were processed

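Single-cell RNA-seq was measured in 10 libraries of cells differentiated towards atrial cardiomyocytes from WTC11, an established human induced pluripotent stem cell line. Per the labels, the cells were wild type or carried 1 (heterozygous) or 2 (homozygous) mutant alleles of TBX5, were differentiated with a commercial atrial kit, and were dissociated with trypsin at day 20 or day 45 for droplet-based 3' libraries with unique molecular identifiers (UMIs). Each genotype had 2 libraries at day 20, and wild-type and heterozygous cells had 2 at day 45; homozygous cells of day 45 were not analysed here. The labels put replicate 1 and replicate 2 of each day in separate batches (1 and 2 at day 20, 3 and 4 at day 45). They name neither a clone nor the lesion in TBX5, and they do not state that replicates were separate differentiations, so p-values measure the spread between these samples, which may be technical.

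Per the submitters' processing notes, reads were processed with Cell Ranger 6.1.1 and genome build hg38. The authors deposited raw UMI counts per gene and cell barcode for 36601 genes, with the libraries of a day joined in a single matrix, and the number at the end of a barcode names the library, per the labels. All barcodes matched a library (0 did not). Whether depth was equalised when the libraries were joined is not given in the sources used here. Gene positions are 1-based and come from GENCODE v29 (GRCh38/hg38), in which 34587 of the genes were found by Ensembl identifier.

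Barcodes were kept with at least 500 genes, at least 1000 UMIs and at most 30% mitochondrial UMIs. Scrublet's automatic threshold failed in most libraries, so cells with a doublet score above the cut-off for the highest 8% of their library were removed (519 to 827 per library, under 8% because scores tied at the cut-off were kept). Cells of a day were normalised, reduced to 30 principal components of 2000 variable genes and clustered with Leiden (resolution 0.8, 20 neighbours; Python 3.11.15, scanpy 1.11.5, leidenalg 0.10.2). A cluster was called "X-like" where at least 50% of the markers fixed for a cell type, and at least 5 of them, were high, meaning at least 10 CPM and 25% of the level in their highest cluster. Clusters of over 50% called doublets, clusters whose median UMI count was under 1/3 of that of their libraries, and clusters with more markers of another type among their leading genes stayed unnamed. This naming rule is the last of 3 versions: it was changed after the clusters and shares had been seen and before any test between genotypes, and the minimum of the summed-marker alternative was changed from 2% to 1% of UMIs in the same way. Clusters with cardiomyocyte markers that stayed unnamed for low UMI counts held 14.6% ± 4.25 (SD, n = 2) of wild-type, 10.3% ± 8.84 of heterozygous and 3.52% ± 2.44 of homozygous cells at day 20, and 5.17% ± 4.96 and 4.32% ± 3.24 of wild-type and heterozygous cells at day 45.

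Cells are not replicates, so raw counts of cardiomyocyte-like cells were summed per library and tested with edgeR 4.0.16 (quasi-likelihood, TMM, filterByExpr; R 4.3.3) at a Benjamini-Hochberg adjusted p of 0.05. All 6 libraries of day 20 shared a fit, day 45 had its own, and the difference of the heterozygous effect between days was tested over all 10. CPM values are means of TMM-scaled values over 2 libraries, and standard errors come from the edgeR coefficients. A count of 0 allows up to 3 counts over the group, which bounds a fold change at 2.84 CPM in homozygous cardiomyocyte-like cells; ratios of 1 to 3 counts are given with 95% counting intervals, and both cover counting error only. Counts simulated from the blocked fit, with its means, batch shifts and spread and with 200 genes changed, were tested with the same code. The simulated batch shift was the same in every genotype, which favours the block. Where batches differ between genotypes in the real data, recovery and false calls may differ from those simulated. For the heterozygous comparison at day 20 (18620 genes), 1.1% of 2-fold and 45.9% of 4-fold changes were recovered without and 73.7% and 95.9% with the replicate block; for the homozygous comparison (18629 genes), 0% and 32.0% were recovered without and 19.2% and 48.0% with it. False calls numbered 0 without the block in every comparison. With it they numbered 8 and 2 in these, 4 for homozygous against heterozygous, 43 for the trend over alleles, 14 at day 45 and 36 for the difference between days, so blocked calls of the last 3 are less secure.

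Replicate numbers pair the samples because the labels give them as batches; deviations of same-numbered libraries from their group means also correlated (0.641 for wild type and heterozygous, 0.255 for wild type and homozygous, 0.344 for heterozygous and homozygous over 8764 genes at day 20, and 0.720 over 7954 genes at day 45). The reported fit has no block, as fixed before the data were examined, and values with the replicate number as a block stand beside it where they change a call over all genes, a list call or the count of such calls by over 1.5 times. The genes named are TBX5, 20 preset genes, the 6 largest rises and falls past the threshold with at least 10 CPM and the same direction in both batches, and up to 3 members of each list with the smallest p. The same rule was also applied to the blocked fit after the data were seen. Other genes are said to have been chosen after their values were seen.

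The 20 gene lists, also fixed in advance, were atrial identity, ventricular identity, sinoatrial node, atrioventricular and fast conduction, atrial fibrillation loci, cardiac transcription factors, ion channels and gap junctions, calcium handling, sarcomere, oxidative phosphorylation, fatty acid oxidation, glycolysis, cell cycle, extracellular matrix, retinoic acid response, natriuretic peptides and wall stress, immediate early and heat shock, hypoxia, ribosomal proteins and mitochondrial transcripts. They were tested with camera (limma 3.58.1, preset correlation 0.01, adjusted over the 20 lists). With an estimated correlation, 0 of the list calls of any comparison remained, and that adjusted p is given with the list calls printed. Shares of cells were compared by exact permutation, and the correlation of comparisons that share controls was set beside 100 simulated sets of unchanged groups, of which 20 were fitted for shared calls. Alternatives were the replicate block, DESeq2 1.42.0 (size factors and Wald test), no filter on low counts, other cell filters, cluster settings and cell definitions, equal cell numbers, fry, and leaving out each library. Levels of day 20 and day 45 were not compared, because day, batch and matrix coincide.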

Results

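Single-cell RNA-seq addressed how atrial cardiomyocytes differ with the number of mutant alleles of TBX5, which encodes a T-box transcription factor needed for heart development. The 10 libraries comprised 2 wild-type, 2 heterozygous and 2 homozygous libraries at day 20 of differentiation and 2 wild-type and 2 heterozygous libraries at day 45. They held 72797812 to 185857470 UMIs at day 20 and 108526851 to 145184256 at day 45, and 7097 to 10107 cells each after filtering. The median cell had 10182 to 16004.5 UMIs in 9 libraries and 6953 in heterozygous replicate 1 of day 20.

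Homozygous cultures held almost no cardiomyocyte-like cells, the cells with high levels of TNNT2, MYH6, TTN and other genes of the contractile apparatus. Their share at day 20 was 59.1% ± 6.37 (SD, n = 2) in wild-type, 61.8% ± 11.7 in heterozygous and 0.429% ± 0.227 in homozygous cultures. The homozygous libraries held 45 and 23 such cells, which gave 0.589% (95% exact binomial interval 0.430 to 0.788) and 0.269% (0.170 to 0.403). Fibroblast-like cells made up 5.5% ± 2.85, 9.50% ± 3.08 and 26.9% ± 8.50, and smooth muscle-like cells 0.748% ± 0.244, 0.606% ± 0.378 and 2.06% ± 1.29. Clusters without a name held 34.0% ± 9.87, 27.6% ± 7.57 and 69.0% ± 10.2. Among these (chosen after the clusters were seen), a cluster led by C7, CCL21, SST and PLAT held 670 and 1757 cells of the homozygous libraries and 20 and 59 of the wild-type ones. A cluster led by ALDH1A1, TMEM88 and LRP2 held 239 and 1403 against 2 and 29.

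The share of cardiomyocyte-like cells had a slope of −29.3 percentage points per mutant allele. With 2 libraries a genotype, this slope is set by the homozygous and wild-type means alone. It does not show a fall with each allele, since the heterozygous mean was 61.8% against 59.1% in wild type. In all, 8 of the 90 arrangements of the 6 libraries gave a slope as large (exact permutation test, two-sided, p = 0.0889). So did 6 of the 36 arrangements within batches (exact p = 0.167). Without heterozygous replicate 2 the exact p was 0.20, and with cells defined by their summed markers it was 0.0444, with a homozygous share of 6.84% ± 0.345. For fibroblast-like cells, whose test was not among those fixed beforehand, the slope was 10.7 points per allele (4 of 90 arrangements, exact permutation p = 0.0444). Within batches 2 of 36 arrangements gave a slope as large (exact p = 0.0556, the smallest p those arrangements can give). This slope too is set by the homozygous and wild-type means alone. At day 45 cardiomyocyte-like cells made up 82.2% and 82.5% of the wild-type libraries and 74.9% and 72.3% of the heterozygous ones, and fibroblast-like cells 5.60% ± 4.92 and 9.86% ± 5.97. The cardiomyocyte-like shares of day 45 depended on the naming rule, whose last version was chosen after shares had been seen. The first version gave 79.0% and 38.2% in wild-type and 60.4% and 36.4% in heterozygous libraries, and the second 52.2% and 73.9% against 54.1% and 59.6%. An exact test of 2 libraries against 2 cannot give a p below 0.333.

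**Figure D1:**
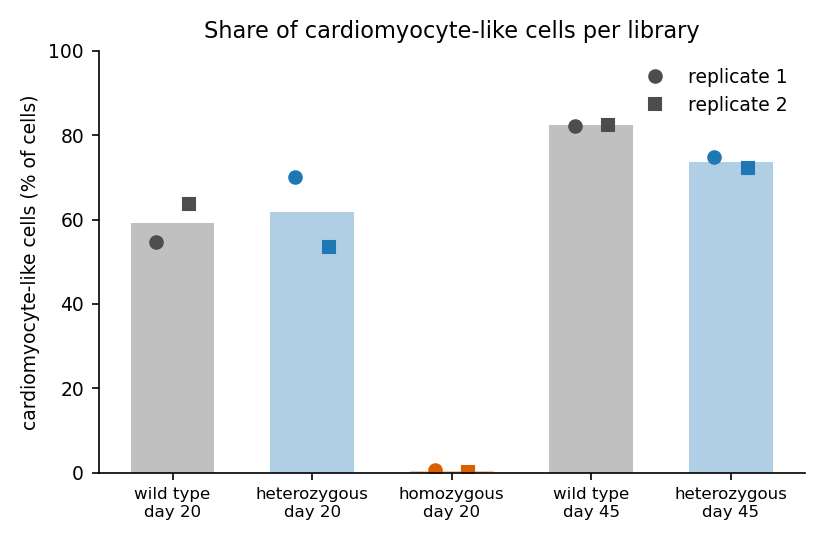
Share of cardiomyocyte-like cells (percent of cells, linear axis from 0) in each library by genotype and day, with points for libraries and bars for group means. The 2 homozygous libraries lie at 0.589% and 0.269%, below all other libraries.

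TBX5 (chromosome 12, 114353931 to 114408442) did not pass the test in any comparison of cardiomyocyte-like cells. Its level at day 20 was 95.7 ± 16.8 CPM (SD, n = 2) in wild-type, 93.8 ± 32.6 in heterozygous and 90.3 ± 21.9 in homozygous cardiomyocyte-like cells. At day 45 it was 90.5 ± 32.1 in wild-type and 101.7 ± 24.1 in heterozygous cells. The 3' tags count transcripts and the labels do not give the lesion, so these levels cannot check the genotype labels.

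DES, which encodes desmin, the intermediate filament protein of muscle (chromosome 2, 219418377 to 219426739), fell in heterozygous cardiomyocyte-like cells at day 20. Its level was 20.2 ± 3.19 CPM (SD, n = 2) against 159.9 ± 33.3 in wild type, a log2 fold change of −2.98 (SE 0.25, edgeR quasi-likelihood test, BH-adjusted p = 0.0341), with −3.03 and −2.92 within the batches. With the replicate number as a block, NR2F1 and NR2F2, nuclear receptors that direct atrial identity, fell as well, along with NPPA, the atrial natriuretic peptide gene. The genes that rose with the block included MYL2, the ventricular regulatory myosin light chain gene, LBH and COL3A1, a fibrillar collagen gene.

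Of 18975 genes tested by edgeR, 1 (DES) passed without the block, 294 had an unadjusted p under 0.05, and DESeq2's Wald test called 20. The block raised the count to 236 (109 higher, 127 lower). DES lost its call without homozygous replicate 1, without homozygous replicate 2, and without both (0 genes each by edgeR). With both left out, the blocked fit called 94. The count was 6 without wild-type replicate 1, 3 without wild-type replicate 2 and 8 without heterozygous replicate 2. Most heterozygous cells of replicate 1 came from clusters 4 and 7 and most of replicate 2 from clusters 0 and 5, whereas wild-type cells came mostly from cluster 2 in replicate 1 and cluster 0 in replicate 2. Cluster 4, led by MYH7, NPPA and MYL3, held 2170 heterozygous against 609 wild-type cells in replicate 1 and 71 against 44 in replicate 2. Genotypes were not compared within these clusters. The heterozygous shifts below therefore cannot be told apart from differences between clusters.

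Genes of atrial identity lay lower in heterozygous cells: the median log2 fold change of the 21 measured members was −0.50 (camera, adjusted p = 1.76e-05, and adjusted p = 0.271 with an estimated correlation). None passed without the block by edgeR (0 of 21, also 0 adjusted over the list alone), and 6 fell with it (9 lower and 1 higher adjusted over the list alone). With the block, NR2F1 had a log2 fold change of −1.57 (BH-adjusted p = 0.000429; −2.69 and −0.57 within batches) and NR2F2 one of −1.13 (0.0038; −1.79 and −0.53). HEY1, a Notch-responsive repressor gene of the atria, had −1.18 (6.33e-05). NPPA stood at 480.6 ± 219 CPM against 878.4 ± 83.8 (SD, n = 2), a blocked log2 fold change of −0.94 (0.00927; −0.56 and −1.33 within batches). MYH6 (−0.54), KCNA5 (−0.50), KCNJ3 (−0.52), GJA5 (−0.86), SLN (0.08) and MYL7 (0.09) passed in neither fit.

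Ventricular identity genes lay higher, with a median of 0.64 over 17 genes (adjusted p = 1.76e-05, and adjusted p = 0.573 with an estimated correlation). With the block 6 rose (7 adjusted over the list alone; without the block 0, and 1 adjusted over the list alone). MYL2 rose with the block (log2 fold change 2.37, edgeR BH-adjusted p = 6.34e-09), at 42.0 ± 57.0 CPM against 6.82 ± 8.95. LBH (1.32, 5.50e-05), HEY2, a ventricular repressor gene (1.28, 0.00973), and PRDM16 (1.00, 0.00896) rose too. Neither MYH7, the slow myosin heavy chain gene (0.68), nor IRX4 (0.64) passed.

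Sinoatrial node genes lay lower, with a median of −0.36 over 14 genes (adjusted p = 4e-05, and adjusted p = 0.573 with an estimated correlation). With the block 2 fell, TBX3, a repressor gene of the conduction system (−1.33, 0.000165), and VSNL1 (−1.41, 1.10e-05). Adjusted over the list alone, 1 was lower without and 6 were lower with the block. SHOX2 (−0.89) and HCN4 (−0.44) did not pass. Among 28 ion channel and gap junction genes (median −0.12, adjusted p = 0.00792, and adjusted p = 0.288 with an estimated correlation, or 0.0878 with the block), CACNA2D2 (−1.45, 8.33e-05) and CACNA1G (−0.98, 0.0056), both calcium channel subunits, fell with the block. The list alone gave 1 lower without and 8 lower with the block.

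Extracellular matrix genes lay slightly higher (32 genes, median 0.07, adjusted p = 0.00858, and adjusted p = 0.573 with an estimated correlation). With the block COL3A1 (1.13, 0.000841), FN1, the fibronectin gene (0.98, 0.003), and 1 other rose and LAMA2 fell (−0.68, 0.0216). Adjusted over the list alone, 1 was higher without the block, and 7 higher and 2 lower with it. Fibroblast-like cells, which carry these genes, made up 9.50% ± 3.08 of these cultures against 5.5% ± 2.85 in wild type. The 36 sarcomere genes had a median of −0.09 (adjusted p = 0.0133, and adjusted p = 0.629 with an estimated correlation, or 0.0698 with the block). With the block MYL2 rose and 3 fell, among them MYOM2 (−1.31, 0.0114) and MYBPHL (−1.01, 0.0114). Heat shock and immediate early genes had a median of −0.14 over 20 genes (adjusted p = 0.00792, and adjusted p = 0.288 with an estimated correlation), and HSPA1A (−1.91, 2.08e-05) and HSPA1B (−0.93, 0.0438) fell with the block.

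The other 13 lists did not pass camera at day 20 in heterozygous cells. With the block, 5 cardiac transcription factor genes rose and 5 fell, 3 atrial fibrillation genes fell, among them NPPA and TBX3, and 3 retinoic acid response genes fell, among them RARRES2 (−1.04, 0.00593). Of the atrioventricular list 2 rose, among them RSPO3 (0.79, 0.00973), and TBX3 and CACNA1G fell. COX6A2, of oxidative phosphorylation (−0.92, 0.00222), ACSL1, of fatty acid oxidation (−0.78, 0.0211), ADM, of hypoxia (−1.31, 8.33e-05), and XIRP2, of wall stress beside NPPA (−1.06, 0.0458), fell. No member of the calcium handling, glycolysis, cell cycle, ribosomal or mitochondrial lists passed in either fit (0 of 23, 20, 44, 82 and 13 by edgeR). For RYR2 and ATP2A2, the calcium release channel and calcium pump genes, the log2 fold changes were −0.17 and −0.42. The median and the mean differed in sign for atrioventricular (0.01 and −0.14), atrial fibrillation (0.00 and −0.10), retinoic acid response (0.03 and −0.09) and cell cycle genes (−0.014 and 0.004). The largest changes with the block also took in CCL21 (2.22, 2.05e-07), SV2C (1.63, 9.88e-08), STAC (1.5, 1.09e-05), RGS4 (1.49, 0.000117) and GBP2 (1.44, 9.12e-05) among rises. Among falls they took in MEG3, a maternally expressed imprinted RNA (−5.17, 5.35e-14), GHRH (−1.83, 2.25e-07) and NFASC (−1.41, 0.0005).

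**Figure D2:**
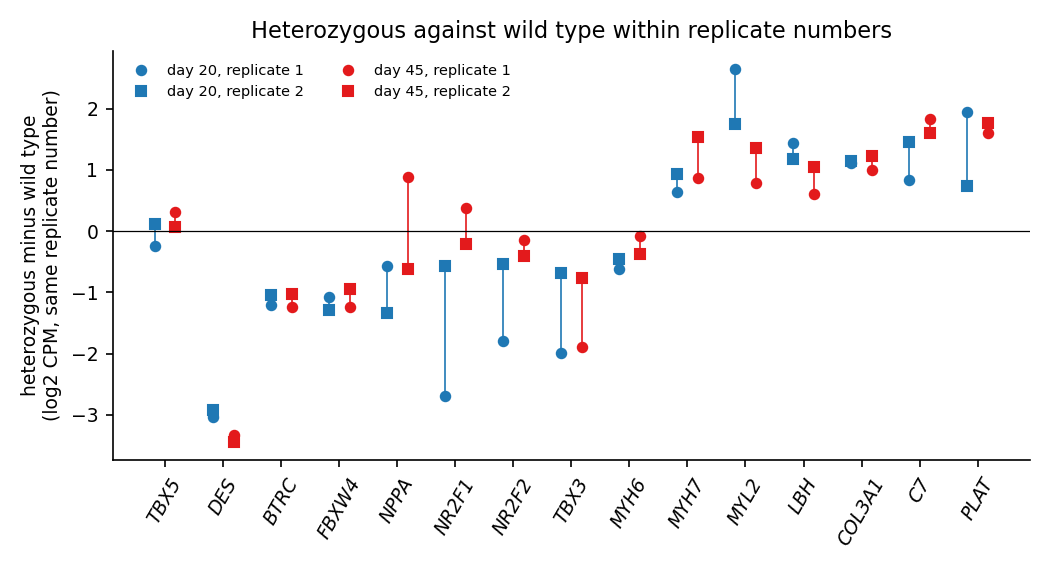
Difference in log2 CPM between the heterozygous and the wild-type library of the same replicate number in cardiomyocyte-like cells, for 15 genes at day 20 and day 45; each point is a batch. DES lies between −2.92 and −3.44 in all 4 batches.

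The few homozygous cardiomyocyte-like cells held little NPPA RNA, at 11.5 ± 1.33 CPM (SD, n = 2) against 878.4 ± 83.8 in wild type. NPPA had a log2 fold change of −6.28 (SE 0.46, edgeR BH-adjusted p = 0.00375), with −6.46 and −6.03 within batches. Genes of contraction fell with it, among them MYL3, a ventricular and slow-muscle myosin light chain gene (−3.99), CSRP3, a sarcomere stress sensor (−2.86), ACTN2, encoding the Z-disc protein alpha-actinin (−2.55), and MYH6, the atrial myosin heavy chain gene (−1.75). FN1 (3.66) and COL3A1 (2.37), which encode matrix proteins, and HAND1, a transcription factor gene of the early heart (2.78), rose. The levels of FN1 were 611.5 ± 29.3 CPM against 48.4 ± 13.3. These values rest on 68 cells with 703004 and 352999 UMIs, and 31 of the 45 cells of replicate 1 lay in cluster 7 and 12 of the 23 of replicate 2 in cluster 5. Most wild-type cells lay in clusters 2 and 0, which had NPPA among their leading genes, whereas clusters 7 and 5 did not. Over cells of all genotypes, MYH6 stood at 1702 and 1244 CPM in clusters 7 and 5 and at 3942 and 3847 in clusters 2 and 0. Genotypes were not compared within these clusters, so differences between clusters and between genotypes cannot be told apart here.

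In all, 146 of 18975 genes passed edgeR (50 higher, 96 lower), and 2466 had an unadjusted p under 0.05. The count was 1126 with the block (462 higher, 664 lower), all 146 among them, and 680 by DESeq2's Wald test (423 higher, 257 lower; 145 of the 146 among them). DESeq2's size factors in edgeR gave 57 higher and 80 lower, and cells by summed markers 966 and 929. The median log2 fold change of all genes was −0.26 with TMM, −0.15 with DESeq2's size factors and 0.02 in the Wald test, and changes here are relative to the TMM scale. No gene passed without homozygous replicate 1 or without homozygous replicate 2 (0 each by edgeR, with 1816 and 2436 at an unadjusted p under 0.05), whereas 405 and 376 passed without heterozygous replicates 1 and 2.

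Sarcomere genes fell most broadly. Of 36 members, 8 fell without the block, 21 adjusted over the list alone and 22 with the block. The median was −1.58, or −1.18 with members at 0 UMIs set at their bound (adjusted p = 9.16e-32, and adjusted p = 0.126 with an estimated correlation). Dilution by RNA of other cells, which would lower genes of cardiomyocytes alike, was not tested as a source of these falls. It was not tested for the calcium handling genes below either. The 12 cardiomyocyte markers, some of them sarcomere genes, had a median of −1.095. The BH-adjusted p was 0.0114 for MYL3, 0.00375 for CSRP3, 0.012 for ACTN2 and 0.0219 for MYH6, whose level was 1077 ± 168.8 CPM against 3622 ± 174.7. MYL7, the atrial regulatory light chain gene (−0.50), did not pass, and MYH7 (−2.07, 0.458) passed only with the block (0.0348), with −3.69 and 0.47 within the batches. Of 23 calcium handling genes 3 fell (8 adjusted over the list alone, and 1 higher and 6 lower with the block; median −0.64, or −0.55 at the bound; adjusted p = 0.000105, and adjusted p = 0.156 with an estimated correlation): SLC8A1, the sodium-calcium exchanger gene (−2.26, 0.014), TRDN, of the calcium release complex (−2.07, 0.0458), and ATP2A2 (−2.01, 0.0354). RYR2 (−1.69, 0.0769) passed only with the block (1.54e-06).

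Of 21 atrial identity genes, NPPA, MYH6 and KCNJ3, a potassium channel gene of the atria, fell (median −1.29, or −1.20 at the bound, adjusted p = 2.71e-06, and adjusted p = 0.126 with an estimated correlation). Adjusted over the list alone, and also with the block, 2 were higher and 7 lower. KCNJ3 had 2 UMIs, a ratio of 0.0101 to 0.302 of wild type. NR2F2 (−3.63, BH-adjusted p = 0.0888) and NR2F1 (−2.58, 0.519) passed only with the block (1.49e-09 and 0.000776). Of 17 ventricular identity genes HAND1 rose (BH-adjusted p = 0.0417), MYL3 and FHL2, a LIM-domain gene (−3.03, 0.00987), fell, and the list did not pass camera (median −1.87, or −1.17 at the bound; adjusted p = 0.177; 4 higher and 3 lower adjusted over the list alone, and 4 and 7 with the block). The sinoatrial list (14 genes, median −1.45, or −0.97 at the bound; adjusted p = 0.000423, and adjusted p = 0.303 with an estimated correlation) had CPNE5 lower, at 3 UMIs (ratio 0.0154 to 0.219), and 5 lower adjusted over the list alone, and 1 higher and 6 lower with the block. TBX3 (−3.3, 0.0543) and HCN4 (−1.92, 0.162) passed only with the block (5.51e-05 and 3.10e-05).

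Of 38 genes at atrial fibrillation loci KCNN2, a calcium-activated potassium channel gene, rose (1.46, 0.0483), and NPPA and MYH6 fell. Adjusted over the list alone 1 was higher and 9 lower, and with the block 1 and 12 (median −1.03, or −0.86 at the bound; adjusted p = 1.38e-07, and adjusted p = 0.156 with an estimated correlation). Among 28 ion channel genes KCNN2 rose and CACNB2, a calcium channel subunit gene (−1.92, 0.0222), fell beside KCNJ3. Of these genes 1 was higher and 8 lower adjusted over the list alone, and 1 and 7 with the block (median −1.36, or −0.53 at the bound; adjusted p = 0.000466, and adjusted p = 0.156 with an estimated correlation). HAND1 was the only cardiac transcription factor gene of 34 past the threshold without the block (3 higher and 5 lower adjusted over the list alone, and 6 and 8 with the block; median −0.47, or −0.41 at the bound; adjusted p = 0.0471, 0.202 as the adjusted p with an estimated correlation, and 0.106 with the block). RSPO3 rose among 13 atrioventricular genes (1.88, 0.0184; list adjusted p = 0.799; 2 higher and 2 lower with the block). NPPA and CSRP3 fell among 13 natriuretic and wall stress genes (median −1.98, or −0.91 at the bound; adjusted p = 0.000466, and adjusted p = 0.303 with an estimated correlation; 1 higher and 2 lower adjusted over the list alone, and 1 and 6 with the block).

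Energy metabolism lists lay lower, beside a median of −0.26 over all genes tested. With the block, glycolysis and hypoxia genes also fell in day 20 clusters 1, 3 and 12 (below), which were not cardiomyocyte-like. Glycolysis had a median of −0.65 over 20 genes (adjusted p = 9.52e-09, and adjusted p = 0.156 with an estimated correlation), and ALDOC, an aldolase gene, fell (−2.12, BH-adjusted p = 0.0318), with 7 lower adjusted over the list alone and 9 with the block. Hypoxia-responsive genes had a median of −0.77 (20 genes, adjusted p = 2.69e-06, and adjusted p = 0.156 with an estimated correlation). Of these 0 passed by edgeR over all genes, 7 were lower adjusted over the list alone and 9 with the block, among them BNIP3 (−1.35) and ENO2 (−1.65). Oxidative phosphorylation (83 genes, −0.33, adjusted p = 4.60e-06, and adjusted p = 0.303 with an estimated correlation) had COX6A2 lower at 1 UMI (ratio 0.000429 to 0.0943). Fatty acid oxidation (26 genes, −0.39, adjusted p = 0.00296, and adjusted p = 0.230 with an estimated correlation) had ACSL1 lower at 3 UMIs (0.0181 to 0.256). In these lists 1 and 4 were lower adjusted over the list alone, and 5 and 4 with the block. Ribosomal protein genes had a median of −0.35 (82 genes, adjusted p = 7.30e-09, and adjusted p = 0.394 with an estimated correlation), and 0 passed by edgeR without and 2 fell with the block, RPS24 (−0.82) and RPL27 (−0.70).

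Of 32 extracellular matrix genes 5 rose and 1 fell (10 and 4 adjusted over the list alone, and also with the block; median 0.36, or 0.40 at the bound; adjusted p = 2.69e-06, and adjusted p = 0.156 with an estimated correlation), in cultures with 26.9% ± 8.50 fibroblast-like cells against 5.5% ± 2.85. FN1 (BH-adjusted p = 0.0102) and COL3A1 (0.0114) rose and LAMA2, a laminin chain gene, fell to 1 UMI (ratio 0.000316 to 0.0696). Of 20 retinoic acid response genes 1 rose and 1, TGM2, a transglutaminase gene, fell (log2 fold change −1.86, adjusted p = 0.0216). The list did not pass (adjusted p = 0.799; 2 higher and 3 lower adjusted over the list alone, and 3 and 4 with the block). Cell cycle (adjusted p = 0.311), immediate early and heat shock (0.663) and mitochondrial (0.420) lists did not pass, with 0 members called by edgeR in each without the block. With it HMGB2 (−1.17) and JUN (−2.13) fell and RRM2 (1.37) and IER2 (0.94) rose. For cell cycle and for immediate early and heat shock the median (−0.11 and 0.09) and the mean (0.08 and −0.09) differed in sign.

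The largest rises were FCMR (4.66, BH-adjusted p = 0.0382), PNOC (4.04, 0.0219), LRRTM1 (4.04, 0.0216), KCNV1 (3.91, 0.0161), RGS4 (3.84, 0.0114) and PHLDA1 (3.70, 0.0388). RGS4 was also a leading gene of fibroblast-like clusters 1 and 19, KCNV1 of unnamed cluster 24, and SST (below) of clusters 6 and 19. RNA from such cells was not tested as a source of these rises. ANGPT1, the angiopoietin 1 gene, had 0 UMIs and was at least 63.7-fold lower, and CLIC5, KCNH7 and PPP2R2B, at 0 UMIs, were at least 8.49-fold, 7.69-fold and 7.26-fold lower. TRH, at 1 UMI, had a ratio of 6.42e-05 to 0.0141, and HAMP, the hepcidin gene, at 3 UMIs, one of 0.00154 to 0.0218. With the block SST (4.91) and SPRR2F (6.11) also rose, and NPPB, the B-type natriuretic peptide gene, NMRK2, DUSP5, VSNL1, MYL2 and IRX4, all at 0 UMIs, fell, at least 23.3-fold, 9.49-fold, 8.38-fold, 8.64-fold, 2.40-fold and 3.02-fold lower.

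**Figure D3:**
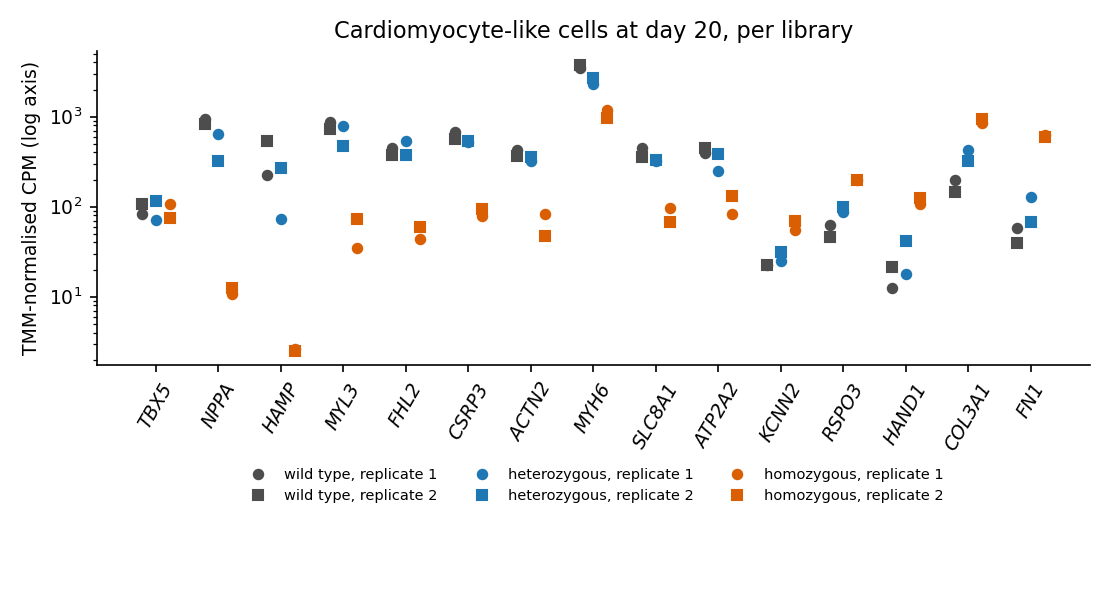
Level of 15 genes in cardiomyocyte-like cells of the 6 day 20 libraries (TMM-scaled CPM, log axis), with a point for each library. NPPA lies at 11.5 CPM on average in homozygous and at 878.4 in wild-type cells, and FN1 at 611.5 and 48.4.

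Homozygous against heterozygous cells, the comparison of 2 mutant alleles with 1, gave 27 genes by edgeR (3 higher, 24 lower). NPPA (−5.41, BH-adjusted p = 0.0109), MYL3 (−3.65, 0.0271), FHL2 (−3.17, 0.0109), CSRP3 (−2.64, 0.0109), ACTN2 (−2.34, 0.0278) and SLC8A1 (−1.96, 0.041) fell, and FN1 (2.65, 0.041), STAC (2.12, 0.041) and MEG3 (7.16, 0.0393) rose. For MEG3 the heterozygous level was itself far below wild type (0.780 ± 0.342 against 32.4 ± 32.2 CPM, SD, n = 2). Against wild type, its log2 fold change in homozygous cells was 1.84. MB, CKM, TCAP and LDB3, muscle genes chosen after their values were seen, fell too (−3.51, −4.25, −2.48 and −1.93). Of 36 sarcomere genes 5 fell, 23 adjusted over the list alone and 21 with the block (adjusted p = 7.91e-35, and adjusted p = 0.132 with an estimated correlation). Ventricular genes lay lower here (17 genes, median −2.29, or −1.73 at the bound; adjusted p = 6.89e-05, and adjusted p = 0.319 with an estimated correlation), with 2 called, 1 higher and 2 lower adjusted over the list alone, and 1 and 7 with the block. The number of lists past camera was 15, and 0 with an estimated correlation. The block also gave 15, but the sinoatrial list lost its call (adjusted p = 0.0379 without and 0.152 with it) and the mitochondrial list gained one (0.0897 and 0.0246). With an estimated correlation the adjusted p was 0.497 for the first without and 0.623 for the second with the block. The count of genes was 652 with the block (244 higher, 408 lower) and 332 by DESeq2's Wald test (190 higher, 142 lower), 0 without either homozygous library, 132 and 125 without wild-type replicates 1 and 2, and 160 and 60 without heterozygous replicates 1 and 2.

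A slope over 0, 1 and 2 mutant alleles passed in 34 genes of cardiomyocyte-like cells (26 rising, 8 falling). Over all cells 1 gene passed, and 0 with the block. A fitted slope does not show that a gene changed with each allele. Among the rises were COL3A1 (1.18 per allele, SE 0.12, edgeR BH-adjusted p = 0.0078), FN1 (1.82, 0.0104), STAC (1.78, 0.00395), RGS4 (1.89, 0.00783), RSPO3 (0.93, 0.0125) and HAND1 (1.36, 0.0494). MYH6 (−0.87), TBX3 (−1.44) and TGM2 (−0.86) fell (0.0453, 0.0453 and 0.0476). Of 32 extracellular matrix genes 4 rose (9 higher and 3 lower adjusted over the list alone, and 9 and 2 with the block; adjusted p = 3.46e-06, and adjusted p = 0.167 with an estimated correlation), beside a fibroblast-like share of 5.5%, 9.50% and 26.9%. Of 36 sarcomere genes 1 fell (17 adjusted over the list alone and 15 with the block; adjusted p = 2.21e-21, and adjusted p = 0.167 with an estimated correlation). The cell cycle list passed only with the block (adjusted p = 0.266 without and 0.0261 with it), and not with an estimated correlation (adjusted p = 0.819 with the block). The count was 609 with the block (288 rising, 321 falling), a fit that also made 43 false calls in simulated data beside 68 and 97 recovered 2-fold and 4-fold changes. It was 425 by DESeq2's Wald test (265 and 160), 329 without heterozygous replicate 2, 65, 76 and 73 without wild-type replicates 1 and 2 and heterozygous replicate 1, and 7 and 2 without homozygous replicates 1 and 2.

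Fold changes of heterozygous and homozygous cells against the same wild-type libraries correlated across 18975 genes (Pearson r = 0.308; genes are not independent replicates), with a covariance of 0.184 and the same sign in 63.7%. Unchanged groups simulated against these controls gave r = 0.138, a covariance of 0.0881 and 57.9%, or r = 0.0906, 0.0357 and 56.1% with the spread of the blocked fit, so the covariance exceeded the simulated one by 0.0962 or 0.149. With the block, 66 genes were higher in both (2.65 for independent lists of 109 and 462), 58 lower in both (4.44 for 127 and 664) and 3 opposite. Values for independent lists ignore the shared wild-type libraries. Simulated groups shared 0, but they hold no changed genes. Neither value therefore shows how many calls the shared controls would add between changed groups. Within batches r was 0.30 and 0.181, each with its own control, and 0.184 and 0.0893 with the control of the other batch. Part of the excess may come from the shared controls. Without heterozygous replicate 1 r was 0.104, and without homozygous replicate 1 it was 0.209. Over genes of at least 10 CPM r was 0.495. No simulated value is given for these 3 settings.

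At day 45, DES was again far lower in heterozygous cardiomyocyte-like cells, at 28.3 ± 5.81 CPM (SD, n = 2) against 293.6 ± 45.2, but it missed the threshold without the block (log2 fold change −3.38, SE 0.22, edgeR BH-adjusted p = 0.0956) and passed with it (0.000179; −3.33 and −3.44 within batches). With the block, TNMD, the tenomodulin gene (2.39, 0.00061), HOPX, a cardiac homeobox cofactor gene (1.53, 0.00489), ACTA1, the skeletal alpha-actin gene (1.5, 0.0321), and MYL2 (1.07, 0.0427) rose. HAMP (−1.40, 0.00489) and the chromosome 10 neighbours BTRC (−1.13, 0.0107) and FBXW4 (−1.10, 0.015) fell. C7 (1.73, 0.00686), PLAT (1.68, 0.00369) and SULT1E1 (1.70, 0.0472) rose and CEBPZOS fell (−1.29, 0.0468).

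Without the block edgeR called 0 of 18356 genes (600 at an unadjusted p under 0.05; 77 by DESeq2's Wald test), and with it 98 (50 higher, 48 lower). The count was 228 without wild-type replicate 1, 206 without wild-type replicate 2 and 1 without heterozygous replicate 1, each leaving a lone library assumed to vary like the other group. Replicates lay in different clusters (0 and 4 mostly replicate 2; 1, 2 and 8 mostly replicate 1), and cluster 2 held 2524 cells of wild-type replicate 1 against 60, 495 and 46 of wild-type replicate 2 and heterozygous replicates 1 and 2.

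**Figure D4:**
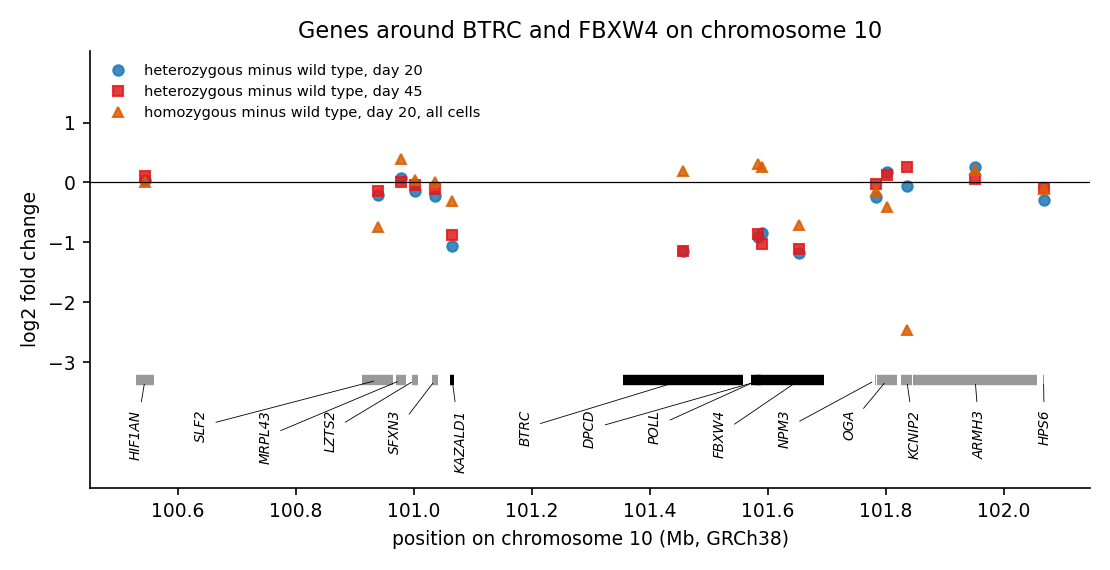
Log2 fold changes in heterozygous cardiomyocyte-like cells at day 20 and day 45 and in homozygous cells (all cells, day 20) against position on chromosome 10, for 5 neighbouring expressed genes from KAZALD1 to FBXW4 (black bars, KAZALD1, DPCD and POLL chosen after their values were seen) and the 5 nearest measured genes on each side (grey bars). The 5 genes have a median of −1.07 and −1.03 in heterozygous cells and the 10 others −0.10 and −0.01.

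Natriuretic and wall stress genes lay higher at day 45 (14 genes, median 0.63, adjusted p = 7.91e-07, and adjusted p = 0.724 with an estimated correlation), as did sarcomere genes (36 genes, 0.20, 1.46e-06, and adjusted p = 0.724 with an estimated correlation) and ventricular identity genes (17 genes, 0.29, 1.99e-05, and adjusted p = 0.724 with an estimated correlation). Their members passing by edgeR numbered 0, 0 and 0 without the block. Adjusted over the list alone, 1 was higher, 1 higher and 1 lower, and 1 higher (with the block 5 higher and 1 lower, 6 and 1, and 6 and 0). With the block 1 (ACTA1), 2 (ACTA1 and MYL2) and 1 (MYL2) rose, and MYH7 stood at 849.4 ± 137.2 CPM against 369.6 ± 62.7 (1.20, BH-adjusted p = 0.0504 with the block). Extracellular matrix genes lay higher (32 genes, 0.25, adjusted p = 0.00151, and adjusted p = 0.915 with an estimated correlation), with COL3A1 higher with the block (1.11, 0.015), beside a fibroblast-like share of 9.86% ± 5.97 against 5.60% ± 4.92. Atrial fibrillation loci (38 genes, 0.09, adjusted p = 0.0189, and adjusted p = 0.724 with an estimated correlation) had PRRX1 (0.86, 0.0287) and SYNPO2L (0.87, 0.0464) higher with the block. Cell cycle (44 genes, 0.13) and mitochondrial (13 genes, 0.23) lists passed too (adjusted p = 0.0212 each, and adjusted p = 0.915 with an estimated correlation).

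Atrial identity (21 genes, median −0.10, adjusted p = 0.429) and the 12 further lists did not pass at day 45, except that hypoxia genes did with the block (20 genes, −0.10, adjusted p = 0.295 without and 0.0471 with it, and adjusted p = 0.966 with the block and an estimated correlation). The log2 fold changes were −0.26 for NPPA, 0.00 for NR2F1, −0.30 for NR2F2, −0.24 for MYH6 and −1.59 for TBX3, none past the threshold in either fit. With the block ATP2B1, a plasma membrane calcium pump gene (−0.81, 0.0228), COX6A2 (−0.55, 0.0468), HSPA1A (−1.71, 0.0462) and EGR1, an immediate early gene (−0.60, 0.0468), fell. The number of lists past camera was 7, 11 without wild-type replicate 1 and 3 without wild-type replicate 2.

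Heterozygous fold changes of the 2 days, which share no library, correlated across 17883 genes (Pearson r = 0.516, across genes), with the same sign in 63.3%. Between single batches r was 0.297 to 0.430 across days, 0.233 within day 20 and 0.326 within day 45. With the block, 24 genes were higher at both days (0.288 for independent lists of 105 and 49), 31 lower (0.333 for 124 and 48) and 0 opposite. Without it 0 were shared, since 1 and 0 genes passed. The 31 included DES, BTRC, DPCD, FBXW4, MEG3, ZNF300, TSPYL5, TRIM61 and CCDC152, which belong to the first and second patterns described below. A difference carried by the heterozygous line apart from TBX5 would also be shared by both days. The agreement between days therefore does not show an effect of TBX5. The correlation was 0.328 without wild-type replicate 2 and 0.302 without heterozygous replicate 1 of day 20, and 0.258 without wild-type replicate 2 and 0.314 without heterozygous replicate 1 of day 45.

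Whether the heterozygous effect itself changed from day 20 to day 45 was tested in 19875 genes, and none passed in edgeR without or with the block or in DESeq2's Wald test (0 each; 83 at an unadjusted p under 0.05 in edgeR). In simulated data this test recovered 0% of 2-fold and 38.1% of 4-fold changes without and 51.5% and 77.3% with the block, so the count of 0 does not show that the effects were alike. Sarcomere (36 genes, median difference 0.29, adjusted p = 8.26e-09), natriuretic and wall stress (14 genes, 0.62, 0.000164), sinoatrial (14 genes, 0.19, 0.00395), atrial identity (21 genes, 0.28, 0.0153), ion channel (28 genes, 0.22, 0.0351) and atrial fibrillation (38 genes, 0.10, 0.0405) lists lay higher at day 45 relative to day 20 by camera. With an estimated correlation the adjusted p = 0.376 for the first 5 and 0.430 for atrial fibrillation loci. Members passing numbered 0 in each of the 6 lists by edgeR, also adjusted over the list alone. With the block, adjusted over the list alone, 3 sarcomere genes were higher and 1 lower, and 3 natriuretic and wall stress genes and 1 sinoatrial gene were higher. The number of lists was 11 with the block, which added ventricular identity (adjusted p = 0.0337), cell cycle (9.66e-05), retinoic acid response (0.0359), immediate early and heat shock (0.0193) and hypoxia (0.00702). With the block and an estimated correlation the adjusted p of these 5 was 0.540, 0.620, 0.239, 0.232 and 0.540. The number was also 11 without wild-type replicate 2 or without heterozygous replicate 1 of day 20.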

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

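No test of this part was chosen after the results were seen. Of 64 genes named at both days, 2 were flagged because every heterozygous library lay below the wild-type library of its batch at day 20 and above it at day 45. For ATP2A2, the calcium pump gene, the heterozygous log2 fold change was larger by 0.53 at day 45 than at day 20 (SE 0.44, edgeR interaction, BH-adjusted p = 1), with −0.67 and −0.22 in the batches of day 20 and 0.15 and 0.11 in those of day 45. For RYR2, the calcium release channel gene, the difference was 0.32 (SE 0.42, edgeR interaction, BH-adjusted p = 1), with −0.20 and −0.12 at day 20 and 0.22 and 0.12 at day 45.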

How the results depend on the processing

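Of 265 recomputed values 156 kept their call or range, 107 moved and 2 became stronger. Although 0 were recorded as reversed, counts of genes and lists and mean shares were compared by size alone and could not be recorded so. Unless stated, the cause was not tested. The tests with all cells and the replicate block, with summed markers for gene counts and their first minimum for shares, with the first and second naming rules, with the low-UMI clusters kept, and without the homozygous libraries were chosen after the data were seen, as was the use of fitted values for the agreement, for which the block was planned. For heterozygous against wild type at day 20, homozygous against wild type, homozygous against heterozygous, the trend over alleles and heterozygous against wild type at day 45, in this order, the replicate block called 236, 1126, 652, 609 and 98 genes and DESeq2's Wald test 20, 680, 332, 425 and 77. No filter on low counts gave 70, 877, 506, 59 and 4. All cells gave 0, 1165, 733 and 1 at day 20, and with the replicate block 0, 3510, 2446 and 0, and 63 at day 45. Cells by summed markers gave 0, 1895, 1188 and 284 at day 20, and the second naming rule and the low-UMI clusters kept gave 0, 521 and 248 in the first 3, where more homozygous cells entered. Without the homozygous libraries the first count was 0, or 94 with the replicate block, and the first naming rule gave 1 at day 45. Leaving out each library gave 0 to 8, 0 to 405, 0 to 160, 2 to 329 and 0 to 228 genes, with a lone library assumed to vary like the other groups. The interaction gave 0 throughout.

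Of the lists, 0 passed with an estimated correlation in any comparison, and 0 with fry except 3 for the trend. The replicate block gave 11 for the interaction, and it changed no list call beyond those printed in the report. Leaving out each library gave 4 to 10, 13 to 16, 13 to 15, 12 to 17 and 3 to 11 lists, and 5 to 11 for the interaction. The agreement of heterozygous and homozygous changes was 0.495 over genes of at least 10 CPM and 0.104 to 0.374 with each library left out, and that between days 0.258 to 0.524. For the share of cardiomyocyte-like cells, the exact permutation p was 0.0444 with summed markers and 0.0222 with their first minimum, and 0.0667 to 0.200 with each library left out. The homozygous mean share was 6.84% and 2.07% with these, 3.95% under the second naming rule and with the low-UMI clusters kept, and 0.269% to 0.589% with each library left out. Depth limits the homozygous profile, in which 68 cells allow no bound under 2.84 CPM.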

Other observations

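The tests of mutant allele number, of a less muscular state, of dilution of NPPA and of the spread between fibroblast-specific genes were chosen after the results were seen, as were the clusters and genes of this part. In the fibroblast-like cluster 1 of day 20, which held cells of every library, RGS5, a pericyte gene (log2 fold change 1.77, edgeR BH-adjusted p = 0.0253), INHBA, an activin subunit gene (1.82, 0.04), ANGPT2, an angiopoietin gene (1.85, 0.042), and G0S2, a lipolysis inhibitor gene (2.79, 0.0247), rose in homozygous against wild-type cells. FST, the follistatin gene (−1.75, 0.0247), LEFTY2, a nodal antagonist gene (−2.35, 0.0247), and STC2 (−1.67, 0.0247) fell. In cluster 3, led by SLN and GABRP, the metallothionein genes MT2A (−3.96, 0.0158), MT1E (−3.73, 0.0195) and MT1X (−2.78, 0.0492) fell, as did FLT1, a VEGF receptor gene (−3.34, 0.0492). In all, edgeR called 22, 35 and 2 genes in clusters 1, 3 and 12, the last led by division genes. Of these 4, 0 and 0 were higher and 18, 35 and 2 lower. With the replicate number as a block the counts were 559 (213 higher, 346 lower), 1418 (656 and 762) and 586 (196 and 390). Of the hypoxia and glycolysis genes 0 passed in any of these clusters without the block. With it 9 of 20, 11 of 20 and 9 of 19 hypoxia genes and 9, 9 and 6 of 20 glycolysis genes fell. Cardiac transcripts fell in these clusters too, among them NPPA (−7.67 in cluster 1, at 0.123 CPM against 25.6), in cultures with a cardiomyocyte-like share of 0.429% against 59.1%. Of the sarcomere genes 3 of 30, 10 of 29 and 0 of 29 fell without the block. With it 16, 21 and 13 fell, and 1 rose in cluster 3. RNA of cardiomyocyte-like cells was not tested as a source of the lower calls in these clusters.

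Over all cells of day 20, TBX5 was lower in homozygous cultures (−2.19, edgeR BH-adjusted p = 0.0143), which held few cardiomyocyte-like cells. TNNT2 (−3.92) and MYH6 (−5.02) fell, and CCL21 (4.10), C7 (3.82) and WT1, an epicardial transcription factor gene (3.94), rose.

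A first pattern, chosen after its values were seen, was that 5 neighbouring expressed genes on chromosome 10 (KAZALD1, BTRC, DPCD, POLL and FBXW4, 101061841 to 101695295) had a median log2 fold change of −1.07 in heterozygous cardiomyocyte-like cells at day 20 and −1.03 at day 45, against −0.10 and −0.01 for their 10 neighbours. Without the block none of the 5 genes passed at either day (lowest edgeR BH-adjusted p = 0.519, for FBXW4 at day 20). With it all passed at day 20, and BTRC, DPCD and FBXW4 at day 45. A makeup or state of the cardiomyocyte-like cells is argued against by 3 other clusters, in which the medians reached no higher than −0.78, and the number of mutant TBX5 alleles by a median of 0.20 in homozygous cells (all cells). None of the 5 genes passed edgeR for heterozygous cells of these clusters in either fit. Loss of a copy of the interval in the heterozygous line was in line with a median of −0.87 over these clusters. It remains a hypothesis, since no DNA was measured.

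A second pattern was that DES and 5 other genes (MEG3, ZNF300, TSPYL5, TRIM61 and CCDC152, chosen after their values were seen) were far lower in heterozygous cells, with a median of −4.73 at day 20 and −5.19 at day 45 for the 5 others. None of the 5 others passed edgeR without the block (BH-adjusted p 0.0725 to 0.378 at day 20 and 0.0956 to 0.841 at day 45), and all passed with it. In wild-type cells of day 20 they lay at 2.37 to 7.59 CPM, except MEG3 at 32.4 ± 32.2 (SD, n = 2). A less muscular state is argued against by sarcomere genes, with medians of −0.089 at day 20 and 0.20 at day 45, and the number of mutant alleles, for the 5 others, by 0.51 in homozygous cells (all cells). For DES, which was at −1.44 in homozygous cardiomyocyte-like cells, the number of mutant alleles remains open. A difference carried by the heterozygous line was in line with medians of −2.64 or lower for the 5 others in 3 other clusters. Which difference this may be was not tested, and the labels name no clone.

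The last pattern was the profile of the 68 homozygous cardiomyocyte-like cells. Dilution by RNA of other cells is argued against as the source of the fall of NPPA. The log2 fold change of NPPA minus the median of 12 cardiomyocyte markers (−1.09) was −5.19. These markers also served to name the clusters, which may have widened the difference. Dilution was not tested for the falls of other genes. The different clusters of homozygous and wild-type cells were not tested as a source. RNA of fibroblast-like cells as the source of the rise of FN1 and COL3A1 remains open. FN1 (715 UMIs, 95% counting interval 663.5 to 769.4) and COL3A1 (1016, 954.5 to 1080) lay above the 201.9 and 468.3 UMIs that the median share implied by 55 fibroblast-specific genes gives (13.4%, quartiles 4.79 to 27.9). That bound, set beforehand, took in counting error but not the spread between genes, and 3 and 7 of the 55 reached the shares of 58.2% and 38.2% that FN1 and COL3A1 need.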
